A study of Homo sapiens with 4 samples.

How the data were processed

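RNA sequencing of a glioma cell line was analysed from 4 libraries, 2 for each of 2 short hairpin RNAs against TRIM59. The cells are labelled as LN229, an established human glioblastoma line, with overexpression of EGFRvIII, a truncated and constitutively active form of the epidermal growth factor receptor. Per the labels' protocols, total RNA was extracted with Trizol and libraries of polyA RNA were made with a TruSeq stranded mRNA kit. Libraries were grouped by the hairpin named in their labels, and the library whose title carries the suffix R was taken as replicate 2 of its hairpin. A library with a control hairpin was not analysed here, so hairpin 1 against hairpin 2 was the comparison that could be made.

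The authors deposited 1 table per library with an FPKM value (fragments per kilobase of transcript, scaled to the sequenced fragments) for each of 63129 gene rows. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm8, a mouse build, whereas all 63129 rows carry human Ensembl gene IDs. The build and annotation used for these values are therefore unsettled, and no coordinates are given. The program that computed the FPKM values, its strand setting and its handling of reads shared between similar genes are not given in the sources used here. Of the rows, 51980 (82.3%) were found by ID in GENCODE 29, which was used for gene type, chromosome, transcript length and GC content, and gene order alone. Symbols are those of the files. All 37 rows of the mitochondrial genome were listed at 0 in every library, so a value of 0 in these files is described as listed at 0 and not as absence of the transcript.

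Depth was not stated, and was read from the FPKM step that 1 fragment adds to single-exon genes. This gave an apparent 30100000 and 34800000 fragments for the shTRIM59-1 libraries and 38800000 and 43000000 for the shTRIM59-2 libraries. The steps served to compare depths, whole counts were not recovered, and differences between hairpins were not tested with a count model. Short transcripts receive very large FPKM values, and rows under 200 bases held between 9.0% and 9.8% of the summed FPKM of a library. Sums of FPKM were therefore not read as depth. For a test of carry-over between libraries, approximate fragments per gene were derived from FPKM, GENCODE 29 length and apparent depth, and compared with the number needed by a Poisson model with variance widened 3.06 times and Bonferroni adjustment, leaving out genes listed at 0.

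Values were analysed as log2(FPKM + 1), and fold changes on this scale understate the change of genes of low abundance. The 15673 rows with a mean of at least 1 FPKM over the 4 libraries were tested, 12729 of them protein-coding. Differences were coded as shTRIM59-1 minus shTRIM59-2 and tested two-sided with limma 3.58.1 (R 4.3.3), with moderated variances and an abundance trend, 2 residual degrees of freedom and a prior of 2.328. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. An exact permutation test of 2 against 2 libraries cannot give a p below 0.33 and was not used. Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists. With an estimated correlation camera's test uses the residual degrees of freedom, 2 here, so it has little power. Members of a list were also adjusted over the list alone. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

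The design, the 23 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The rule named TRIM59, EGFR, STAT3 and PTPN2, then the 12 genes with the largest positive and the 12 with the largest negative difference among those past the threshold with both libraries of a hairpin above both of the other, and up to 4 members per list with the largest differences. Rows without a gene name were skipped, and some genes that the rule names are not reported here. A further 10 lists, further protein-coding genes and a fit of protein-coding genes alone were chosen after the values were seen. Genes whose level could show the sex of the cells' donor were left out of all gene-level tables.

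The fit was tested on simulated values for the same 15673 rows with the spread of these libraries, 200 of them changed. It recovered 59% of changes of log2 size 1 and 12% of changes of log2 size 0.5, and called 0 of 15473 unchanged rows. The changed rows were drawn from the more abundant ones. In the data 11720 rows were called, which makes the Benjamini-Hochberg cutoff less strict than in the simulation. These shares therefore do not give the power or the false calls of the real fit. The median estimate for a change of 1 was 1. A simulated shifted list had an adjusted p of 2.19e-30 and an unshifted list 0.0925 (camera, preset correlation). Simulated rows were drawn independently, and most had no difference between hairpins, unlike the rows of the data. These 2 values therefore do not give the power or the false calls of the list test in the data.

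Before averaging, the libraries of a hairpin were compared with sampling noise at the apparent depths. The median squared deviation was 2.75 times sampling noise for shTRIM59-1 and 3.06 times for shTRIM59-2, so they were not merged as the same library deposited again. Repeat libraries of the same RNA would also exceed sampling noise, so this does not show that they are independent, and they are counted as 2 replicates each because they are labelled as separate samples. The alternatives were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, rescaling to TPM, median scaling, quantile normalization, a block for the title suffix, limma without the trend, leaving out each library in turn, and protein-coding genes alone. Comparisons of count-based tools were left out because the files hold no counts.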

Results

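Expression profiles were obtained from cells labelled as EGFRvIII-overexpressing LN229 glioblastoma cells, carrying either of 2 short hairpin RNAs against TRIM59, an E3 ubiquitin ligase. Each hairpin was represented by 2 libraries. The study asked how knockdown of TRIM59 changes gene expression in these cells. With both hairpins aimed at the same gene and no control library analysed here, the comparison addresses how far the cells carrying the hairpins differed from each other, and not the effect of the knockdown. Apparent depth was 30100000 and 34800000 fragments for shTRIM59-1 and 38800000 and 43000000 for shTRIM59-2. At 1 FPKM or more, 12004 and 11983 protein-coding genes were detected with shTRIM59-1 and 12655 and 12649 with shTRIM59-2. The labels do not say that libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

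TRIM59 itself was measurable with both hairpins. Its level was 8.31 ± 0.43 FPKM (SD, n = 2) with shTRIM59-1 and 12.7 ± 0.0634 FPKM with shTRIM59-2, a log2 difference of -0.56 (SE 0.06, adjusted p = 0.0016, limma). The libraries measured 8.61 and 8 FPKM against 12.8 and 12.7 FPKM. Without a control library these values do not give the degree of knockdown. EGFR was also lower with shTRIM59-1, at 9.16 ± 0.521 against 21.8 ± 0.187 FPKM, a log2 difference of -1.17 (SE 0.06, adjusted p = 1.6e-04). Of expressed protein-coding genes, 30.1% and 32.3% lay below EGFR in the shTRIM59-1 libraries, and 60.5% and 61.1% in the shTRIM59-2 libraries. The labels name overexpression of a truncated EGFR variant. These gene-level values do not separate it from EGFR itself, and how its shorter transcript was counted is not known. Reads of the variant that were counted to this row are part of these values. EGFR lay above no more than 61.1% of expressed protein-coding genes in any library. This argues against a very high level of variant transcripts, as far as they were counted to this row. Without cells that lack the variant, the values do not test overexpression relative to such cells. STAT3, a transcription factor downstream of EGFR and cytokine receptors, was higher with shTRIM59-1, at 47.3 ± 0.444 against 29.6 ± 0.559 FPKM (log2 difference 0.66, SE 0.04, adjusted p = 2.5e-04). PTPN2, which encodes the phosphatase TC45, was at 10.3 ± 0.0445 and 12.5 ± 0.464 FPKM (log2 difference -0.27, SE 0.06, adjusted p = 0.014). The PTPN2 difference no longer passed the threshold without shTRIM59-1 replicate 1 (log2 difference -0.27), shTRIM59-1 replicate 2 (-0.26) or shTRIM59-2 replicate 2 (-0.23).

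**Figure D1:**
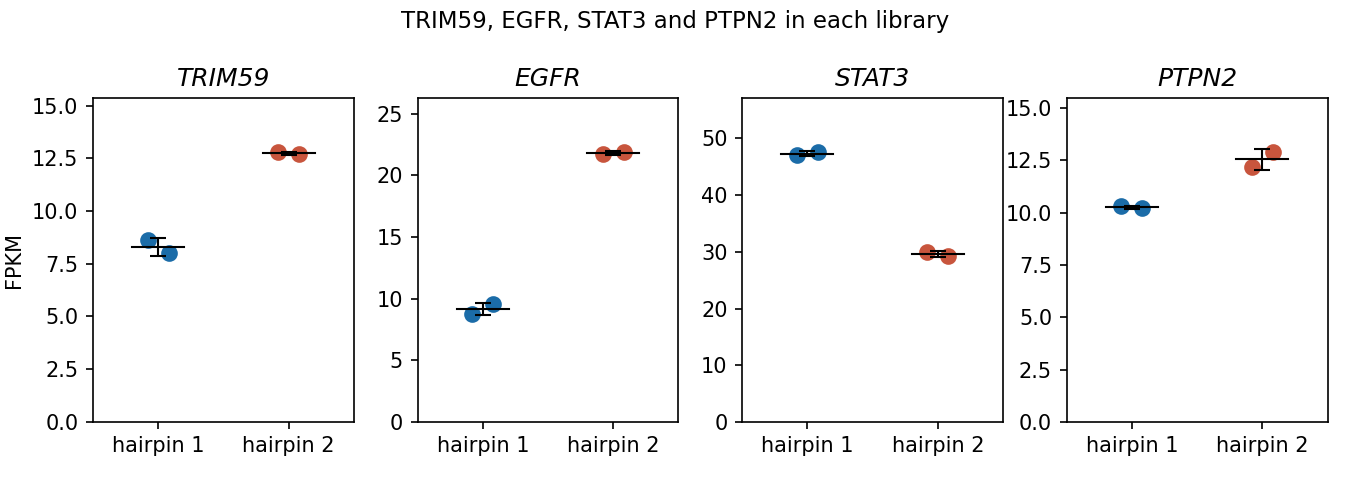
FPKM (vertical axes, each from 0) of TRIM59, EGFR, STAT3 and PTPN2 in the 2 libraries of each hairpin; points are libraries, and the lines and bars are the mean and SD (n = 2). TRIM59 and EGFR lie lower with hairpin 1 (8.31 against 12.7 FPKM and 9.16 against 21.8 FPKM), and STAT3 lies higher (47.3 against 29.6 FPKM).

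The expression profiles of the hairpins differed across most of the transcriptome. Of 15673 tested rows, 11720 (74.8%) passed the threshold, with 5561 higher and 6159 lower in shTRIM59-1 cells. A difference of at least 2-fold was found for 4454 of these, 2177 higher and 2277 lower. The libraries of the hairpins did not overlap for 87.9% of tested rows, against 33.3% by chance. Protein-coding genes made up 9945 (84.9%) of the rows that passed. Across protein-coding genes, which are not independent replicates, Pearson's r was 0.995 between the shTRIM59-1 libraries, 0.996 between the shTRIM59-2 libraries, and 0.808 to 0.81 between hairpins. Among 1035 protein-coding genes of at least 100 FPKM, the robust SD of the log2 difference was 0.076 and 0.08 within hairpins and 0.787 to 0.809 between them. With a minimum mean of 5 FPKM, the number of genes at least 2-fold apart was 2795.

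**Figure D2:**
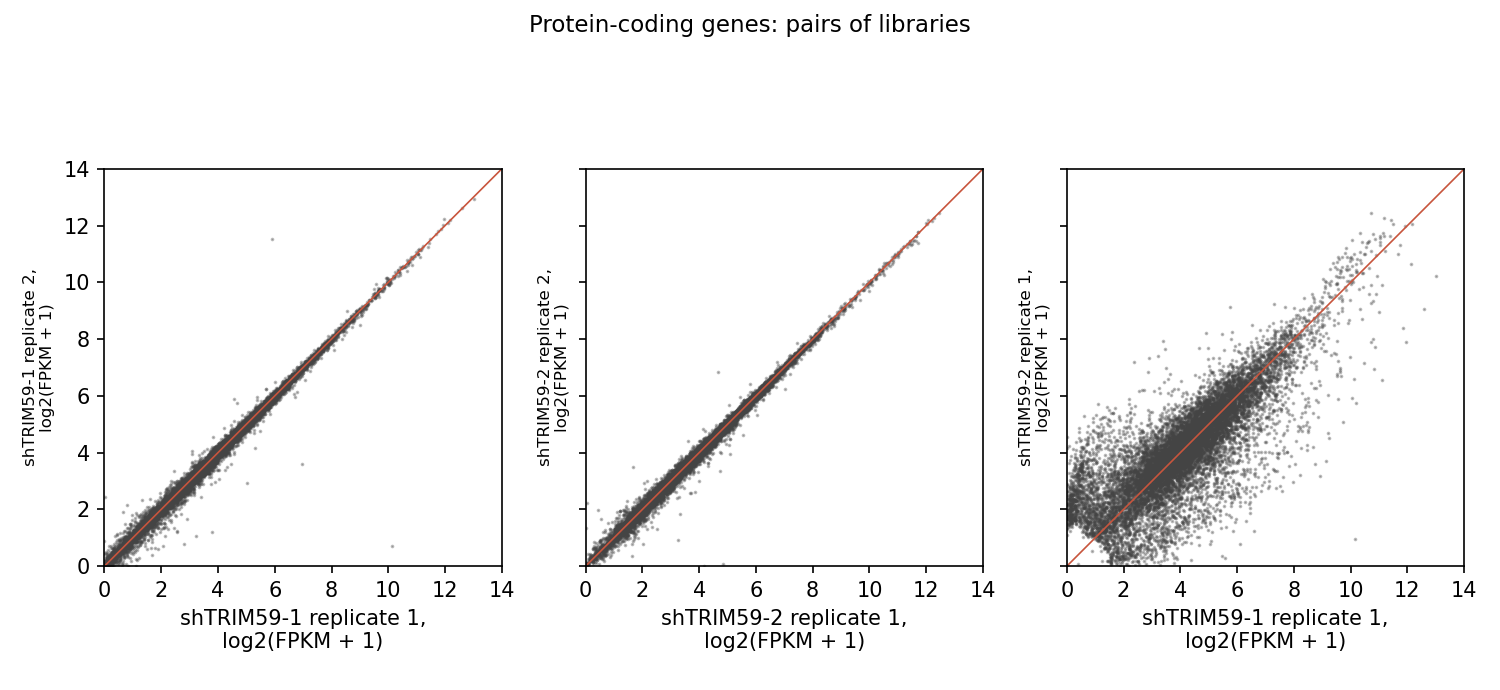
Each point is a tested protein-coding gene, placed by its log2(FPKM + 1) in the libraries named on the axes, and the line marks equal values. Points lie close to the line within a hairpin (Pearson's r across genes 0.995 and 0.996) and scatter widely between hairpins (0.809).

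S100B, SERPINA3 and APOD were among the genes with the largest differences toward shTRIM59-1. S100B, a calcium-binding protein of glial cells, stood at 489 ± 4.61 FPKM against 8.19 ± 0.17 FPKM with shTRIM59-2 (log2 difference 5.74, SE 0.04, adjusted p = 1.5e-05). SERPINA3, a serine protease inhibitor of the acute phase response, stood at 565 ± 1.07 against 12.7 ± 0.973 FPKM. APOD, a lipid-binding apolipoprotein, was at 68.7 ± 0.93 against 0.716 ± 0.0252 FPKM. The collagen genes COL11A1 (416 ± 22.5 against 11.8 ± 1.09 FPKM) and COL8A1 (306 ± 14.4 against 9.09 ± 1.04 FPKM) were in the same set, as were S100A1 (255 ± 8.57 against 6.71 ± 0.161 FPKM) and the cell adhesion gene CHL1 (40.1 ± 3.9 against 0.393 ± 0.143 FPKM). EXTL1 was at 96.5 ± 2.49 against 1.47 ± 0.123 FPKM and SCRG1 at 44.3 ± 3.07 against 0.241 ± 0.0221 FPKM. For these 9 genes the log2 difference ranged from 4.88 to 5.74. The non-coding LINC00511 measured 154 and 1775 FPKM in the shTRIM59-1 libraries and 10.3 and 10.7 FPKM in the others, and its call was lost without either shTRIM59-2 library (log2 difference 5.49 without replicate 1 and 5.54 without replicate 2). RNU1-106P, a pseudogene of the U1 small nuclear RNA, measured 20 and 35.5 FPKM and was listed at 0 in both shTRIM59-2 libraries. TF (transferrin; 76.2 ± 3.33 against 1.82 ± 0.293 FPKM) and MIA (595 ± 3.1 against 22 ± 0.291 FPKM) came next among protein-coding genes, and were chosen after their values were seen.

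JAG2 and CDKN2A were among the genes with the largest differences in the other direction. JAG2, a Notch ligand, was at 0.467 ± 0.0907 FPKM with shTRIM59-1 and 39.2 ± 0.957 FPKM with shTRIM59-2 (log2 difference -4.78, SE 0.08, adjusted p = 2.1e-05). CDKN2A, which encodes the cell cycle inhibitors p16 and ARF, was at 10.2 ± 0.886 against 256 ± 17.9 FPKM (log2 difference -4.53, SE 0.08, adjusted p = 2.3e-05). CYBA, a subunit of NADPH oxidase, was at 5.6 ± 1.31 against 160 ± 0.817 FPKM, and DMKN at 5.02 ± 1.28 against 145 ± 0.111 FPKM. PCSK1N was at 1.92 ± 1.09 against 54.8 ± 4.41 FPKM, and ASS1, an enzyme of arginine synthesis, at 1.12 ± 0.092 against 39.7 ± 1.12 FPKM. PPP1R14A was listed at 0 in both shTRIM59-1 libraries and measured 22.4 and 24.7 FPKM in the others. A further 5 rows of small RNAs, all listed at 0 in both shTRIM59-1 libraries, were named by the same rule. They were MIR221 (2836 and 5695 FPKM with shTRIM59-2), RNU4-2 (1895 and 3158 FPKM), SNORA75 (471 and 509 FPKM), RNVU1-14 (82.4 and 45.1 FPKM) and RNU1-120P (46.6 and 41 FPKM). These RNAs are under 200 bases, where FPKM values are inflated and polyA libraries capture few molecules. The protein-coding genes that followed, chosen after their values were seen, included DPYSL5, EEF1A2, BEX5 and PPP2R2C, with log2 differences from -4.24 to -4.19.

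Interferon-stimulated genes were higher in shTRIM59-1 cells as a group. Of 27 measured members, 24 rose, 1 fell and 2 did not pass the test relative to shTRIM59-2, with the same counts adjusted over the list alone. The median log2 difference was 2.80 (camera, adjusted p = 3.0e-08; adjusted p = 0.26 with an estimated correlation). OAS1 was at 284 ± 23.2 against 14.2 ± 3.66 FPKM, IFI6 at 4353 ± 574 against 257 ± 26.6 FPKM, OAS2 at 100 ± 0.625 against 5.97 ± 0.0603 FPKM and XAF1 at 157 ± 0.87 against 9.93 ± 0.623 FPKM. In all, 21 of 23 lists had enough measured members for a test, and 8 were called, 7 higher and 1 lower with shTRIM59-1. With an estimated correlation 0 lists were called by camera, with adjusted p-values of 0.26 to 0.32 for those 8, and 3 lists had an unadjusted p under 0.05. The estimates for those 8 lay between -0.03 and 0.09, and those of the interferon (-0.03) and ribosomal (-0.01) lists were below the preset 0.01. This form of the test rests on 2 residual degrees of freedom, so it could call few lists whatever the correlation. It does not decide whether correlation between genes lies behind the calls. The fry test, which asks whether the members of a list move on balance 1 way and does not compare them with other genes, called 20 lists.

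Genes induced by EGFR and MAPK signalling were higher with shTRIM59-1, opposite in direction to EGFR itself. Of 23 members 18 rose, 0 fell and 5 did not pass, and adjusted over the list alone 18 were higher and 1 lower. The median log2 difference was 1.74 (camera, adjusted p = 5.8e-06; adjusted p = 0.32 with an estimated correlation). The phosphatase gene DUSP6 was at 84.7 ± 3.9 against 4.41 ± 0.922 FPKM, the EGFR ligand gene TGFA at 173 ± 2.52 against 14.5 ± 0.188 FPKM, and FOSL1 at 344 ± 1.24 against 30.5 ± 0.0631 FPKM. STAT3 target genes were also higher, with 19 risen, 5 fallen and 2 not passing of 26, the same counts adjusted over the list alone, and a median of 1.25 (camera, adjusted p = 7.4e-04; adjusted p = 0.32 with an estimated correlation). MMP2, a matrix protease, was at 1171 ± 22.5 against 53.9 ± 0.745 FPKM and the receptor gene OSMR at 30 ± 0.798 against 2.74 ± 0.0953 FPKM. MYC went the other way, at 11.2 ± 0.424 against 98 ± 2.21 FPKM. A list of 10 genes around TRIM59, EGFR and STAT3 had been chosen from textbook knowledge. Of these 3 were higher, 5 were lower and 2 did not pass, likewise adjusted over the list alone (median -0.23, camera adjusted p = 0.53). IL6ST, the shared receptor subunit of the interleukin 6 family, was at 33.4 ± 8.06 against 11 ± 1.59 FPKM, and JAK2 at 4.14 ± 0.29 against 1.41 ± 0.0668 FPKM.

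Mesenchymal and matrix genes were higher in shTRIM59-1 cells, with 18 risen, 4 fallen and 2 not passing of 24 (median 1.85; camera, adjusted p = 6.7e-05; adjusted p = 0.28 with an estimated correlation). SPARC was at 1687 ± 197 against 113 ± 14.5 FPKM, CD44 at 363 ± 5.93 against 26.4 ± 0.867 FPKM and fibronectin, FN1, at 321 ± 2.09 against 29.8 ± 0.181 FPKM. Neural and glial progenitor genes were higher too, with 10 risen and 3 fallen of 13 (median 1.96; camera, adjusted p = 0.01; adjusted p = 0.32 with an estimated correlation). FABP7 was at 41.8 ± 0.227 against 1.39 ± 0.183 FPKM, PTPRZ1 at 41.9 ± 0.444 against 2.84 ± 0.514 FPKM and nestin, NES, at 151 ± 2.07 against 15.1 ± 0.213 FPKM. NF-kB and cytokine genes showed 16 risen, 2 fallen and 2 not passing of 20 (median 1.15; camera, adjusted p = 8.2e-04; adjusted p = 0.32 with an estimated correlation), with CCL2 at 456 ± 0.866 against 54.6 ± 0.601 FPKM. Genes of the ATF4 and ER stress list showed 17 risen, 5 fallen and 2 not passing of 24, against 17 and 6 adjusted over the list alone (median 0.53; camera, adjusted p = 0.011; adjusted p = 0.32 with an estimated correlation). DDIT3 was at 101 ± 6.22 against 21.9 ± 0.242 FPKM. For the matrix, progenitor and NF-kB lists the counts adjusted over the list alone were the same.

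Cytosolic ribosomal protein genes were lower in shTRIM59-1 cells. Of 36, 31 fell, 1 rose and 4 did not pass, with the same counts adjusted over the list alone (median -0.71; camera, adjusted p = 1.1e-06; adjusted p = 0.26 with an estimated correlation). RPL5 was at 659 ± 0.173 against 1656 ± 8.81 FPKM and RPS2 at 1338 ± 72.7 against 3459 ± 101 FPKM. These genes have many processed pseudogenes, and how reads shared with them were divided is not known.

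Lists of proliferation and metabolism were not called. Of 26 mitosis genes, 11 were higher, 6 lower and 9 did not pass (median 0.14; camera, adjusted p = 0.23), with CENPF at 55.3 ± 4.92 against 22.1 ± 0.208 FPKM and AURKB at 70.4 ± 1.72 against 132 ± 2.82 FPKM. Of 26 DNA replication genes, 7 were higher, 18 lower and 1 did not pass (median -0.41, adjusted p = 0.093), and of 26 oxidative phosphorylation genes 5 were higher, 15 lower and 6 did not pass (median -0.41, adjusted p = 0.058). The DNA replication list was called with no filter (median -0.41) and with quantile normalization (-0.58). The oxidative phosphorylation list was called with no filter and at a minimum of 5 FPKM (both -0.41), with quantile normalization (-0.64) and without shTRIM59-2 replicate 2 (-0.34). The p53 target list had 10 higher, 6 lower and 5 not passing (median 0.17, adjusted p = 0.23), with DDB2 at 77.4 ± 2 against 16.8 ± 1.1 FPKM and BTG2 at 5 ± 0.127 against 17.2 ± 0.513 FPKM. Hypoxia and glycolysis genes had 10 higher, 7 lower and 7 not passing (median 0.13, adjusted p = 0.28), with GAPDH at 4389 ± 53.5 against 1596 ± 21.3 FPKM. Cholesterol synthesis genes had 5 higher, 8 lower and 9 not passing (median -0.10, adjusted p = 0.52). Counts adjusted over the list alone were the same for these 6 lists.

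Stress and early response lists were split in direction. Immediate early genes had 10 higher, 6 lower and 2 not passing (median 0.68; camera, adjusted p = 0.24). Heat shock genes had 5 higher, 8 lower and 1 not passing, with a median of -0.22 and a mean of 0.01 (adjusted p = 0.53). HSPB1 was at 379 ± 17.3 against 28.7 ± 0.027 FPKM and HSPA1B, which shares nearly all its sequence with HSPA1A, at 27.9 ± 0.997 against 296 ± 2.29 FPKM. Of 14 replication-dependent histone genes 7 were below a mean of 1 FPKM, and of the 7 measured 5 were higher and 2 lower (median 0.73, camera adjusted p = 0.27). As the libraries are of polyA RNA, these values cover only polyadenylated transcripts of these genes. Adjusted over the list alone, the counts of these 3 lists were the same.

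The 8 endothelial markers had no measured member, the highest mean in either hairpin being 0.294 FPKM. Of 12 immune markers 2 were measured and the list was not tested, with CD68 at 27.5 ± 0.375 against 3.44 ± 0.137 FPKM. Of 4 measured epithelial markers, 3 were lower with shTRIM59-1 and 1 did not pass (median -1.48; camera, adjusted p = 0.093), with EPCAM at 0.0902 ± 0.05 against 3.26 ± 0.611 FPKM, CDH1 at 0.103 ± 0.0483 against 3.28 ± 0.286 FPKM and KRT8 at 43 ± 6.24 against 86.7 ± 4.57 FPKM. KRT18, which did not pass, was at 51.1 ± 2.75 and 55.8 ± 0.308 FPKM. Of 6 measured fibroblast and pericyte markers 4 were higher, 1 was lower and 1 did not pass (median 1.24, adjusted p = 0.24), with LUM at 38.8 ± 3.43 against 4.06 ± 0.252 FPKM and COL1A1 at 4.22 ± 0.925 against 24.1 ± 0.917 FPKM. Of 5 genes linked to known alterations of LN229, 2 were higher, 2 lower and 1 did not pass (median -0.35, adjusted p = 0.58). Besides CDKN2A, these included CDKN2B at 0.126 ± 0.0162 against 4.69 ± 0.0523 FPKM. MTAP was at 42.2 ± 1.3 against 35.8 ± 2.19 FPKM, and its call was lost after rescaling to TPM (log2 difference 0.08), with quantile normalization (0.13), and without shTRIM59-1 replicate 1 (0.26), shTRIM59-1 replicate 2 (0.20) or shTRIM59-2 replicate 1 (0.17). Adjusted over the list alone, the counts of the immune, epithelial, fibroblast and LN229 lists were the same.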

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

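The fit of protein-coding genes alone was the alternative chosen after the data were seen. Over the alternatives the number of genes that differed between hairpins lay between 8776 (minimum mean of 5 FPKM, which tests fewer genes) and 13801 (no filter), against 11720 as reported. Leaving out 1 library at a time gave 10279 to 10634 genes, with the lone library of a hairpin assumed to vary like the others. Protein-coding genes alone gave 10241. The number at least 2-fold apart fell to 2795 at a minimum mean of 5 FPKM, where fewer genes of low abundance enter, and stayed within 1.5 times of 4454 under the other alternatives. TRIM59 kept its direction and its call throughout, and 8 to 10 of the 21 lists were called. No gene or list changed direction with a call. Among named genes, 13 gene and alternative pairs lost a call and 2 gained one against 1859 that did neither, and 6 list and alternative pairs gained a call against 266. Those of HOXC11 (log2 difference -0.35 without shTRIM59-2 replicate 1) and HOXC10 (0.24 after rescaling to TPM, 0.33 without shTRIM59-2 replicate 2) concern genes of the lists added later. KRT18 gained a call with quantile normalization (-0.25) and without shTRIM59-1 replicate 2 (-0.18). The cause was not tested for these. Rescaling to TPM moved the median difference of all rows from -0.052 to -0.187, and the share of higher calls from 47.4% to 39.2%. Higher calls fell from 5561 to 4216 and lower calls rose from 6159 to 6533, so small differences of either sign depend on the scaling. This rescaling divides by sums of FPKM, which short rows inflate. Replicate numbers do not pair the libraries by their labels, and the differences between the library with and without the suffix R correlated at 0.152 across genes between the hairpins. With the suffix as a replicate block 11860 genes were called. Comparisons of edgeR with DESeq2 were not run, since the files hold no counts. Depth limits the rarest genes most. Simulated changes of log2 size 0.5, placed in more abundant rows, were recovered in 12% of rows. Only 200 rows were changed there, against 11720 called in the data, so the simulated cutoff was stricter and the 12% does not give the power of this fit.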

Other observations

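Tests chosen after the result was seen were those of the added gene lists, of noise of single libraries, of GC content and length, of the level of CDKN2A, of its paralog CDKN2B, and both tests of carry-over over genes of at least 10 FPKM. Genes of antigen presentation were much more abundant with shTRIM59-1. Of 12 MHC class II genes 12 were higher (median log2 difference 3.90; camera, adjusted p = 1.2e-06; adjusted p = 0.22 with an estimated correlation), with HLA-DRA at 849 ± 4.51 against 33.7 ± 0.688 FPKM (SD, n = 2) and CD74 at 2239 ± 67.1 against 94.8 ± 2.53 FPKM. Of 15 MHC class I and peptide loading genes 14 were higher and 1 lower (median 2.14, adjusted p = 8.8e-06; adjusted p = 0.18 with an estimated correlation), with B2M at 8054 ± 326 against 1148 ± 60.6 FPKM. HLA genes share sequence with each other, so their single values are uncertain. Of 20 genes of a list of S100 and annexin genes, which also holds the galectin genes LGALS1 and LGALS3, 17 were higher, 2 lower and 1 did not pass (median 2.18, adjusted p = 1.1e-05; adjusted p = 0.18 with an estimated correlation), with S100A6 at 3714 ± 27.4 against 340 ± 6.32 FPKM.

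Lineage genes differed as well. Of 19 glial and neural crest genes 15 were higher with shTRIM59-1, 2 lower and 2 did not pass (median 2.46; camera, adjusted p = 2.5e-05; adjusted p = 0.22 with an estimated correlation), with the transcription factor SOX10 at 421 ± 14.7 against 17.4 ± 0.368 FPKM and the receptor ERBB3 at 141 ± 2.36 against 5.84 ± 0.227 FPKM. Of 12 melanocyte genes 5 were measured, of which 4 were higher and 1 did not pass (median 1.67, adjusted p = 0.022; adjusted p = 0.36 with an estimated correlation), while the other 7 were below a mean of 1 FPKM and did not all go the same way, with MLANA between 0.114 and 0.622 FPKM. Of 10 HOXA genes 10 were lower (median -1.74, adjusted p = 5.9e-04; adjusted p = 0.22 with an estimated correlation), with HOXA9 at 3.98 ± 0.376 against 41.7 ± 1.45 FPKM. The HOXB (median -0.88, adjusted p = 0.068), HOXC (-0.07, 0.9), HOXD (-0.38, 0.48) and neuronal (-1.38, 0.089) lists were not called. In the neuronal list EEF1A2 was at 8.38 ± 0.141 against 175 ± 10.9 FPKM. Of these 10 added lists 6 were called. For camera with an estimated correlation, which rests on 2 residual degrees of freedom, the lowest adjusted p was 0.18. The estimates were 0.52 for the melanocyte and 0.27 for the MHC class II list, well above the preset correlation. The adjusted p-values of these lists at the preset correlation may therefore be too small. The other called lists had estimates of 0.09 (glial and neural crest), 0.01 (HOXA), -0.01 (MHC class I) and -0.04 (S100 and annexin). S100B is in more than 1 of the added lists.

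As a source of the wide difference between the hairpins, noise of single libraries is argued against by a spread between hairpins 10.01 times the wider spread within a hairpin among abundant genes, and scaling by a ratio of 1.0 of calls under quantile normalization to those reported. An interferon response stays open: leaving out the interferon list kept 0.999 of the spread, but 27 of 15673 rows are too few to move it, so that test is void. Neighbouring genes shifted together: over 113 autosomal windows of 100 genes, in GENCODE 29 order, the SD of window medians was 0.299 against 0.098 with shuffled positions, a ratio of 3.04 (permutation p = 0.001, the smallest that 1000 shuffles can give), which GC content and transcript length left at 3.0. Within hairpins, where no difference of cells is labelled, the ratios were 1.76 and 1.89, with SDs of 0.023 and 0.025. Genomes that differ in chromosome copies may lie behind the libraries of the hairpins, with median differences of 0.485 on chromosome 20 and -0.367 on chromosome 21, while an effect of either hairpin on these cells stays open and untested without a control.

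CDKN2A was abundant in libraries labelled as LN229, a line generally described as having a homozygous deletion of this gene. It measured 244 and 269 FPKM with shTRIM59-2, above at least 97.5% of expressed protein-coding genes and with CDKN2B at no more than 0.019 of its level, which argues against reads from that paralog, so cells other than a CDKN2A-deleted LN229 may have given these libraries. With shTRIM59-1 CDKN2A stood at 4.0% of its shTRIM59-2 level. Counts of genes under 0.5 of that share do not settle whether this was carry-over between libraries: the planned count was 0 of 2122 genes of at least 50 FPKM, but CDKN2A ranks 3 from the lowest share among them, which leaves that test void, and over 7825 genes of at least 10 FPKM the count was 14, with 1 gene listed at 0, between the bounds of 5 and 20 of the planned test. A further test left out genes listed at 0. Of 7823 genes, 3 had fewer shTRIM59-1 fragments than uniform carry-over would give at 3.55%, the lowest CDKN2A share between libraries. They were JAG2 (175 against 518), PPP2R2C (22 against 185) and KIF1A (113 against 293). Uniform carry-over as the only source of CDKN2A there would leave no gene clearly below that number, so these genes argue against it. The bound written for excluding it was 5 genes and was not reached. Carry-over that differs between genes, or that gave only a part of the CDKN2A reads, is left open.

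Some rows of high FPKM disagreed between the libraries of a hairpin. There were 99 rows with a mean of at least 10 FPKM that differed over 4-fold, 6 of them protein-coding. Of the 69 with a length in GENCODE 29, 56 were under 200 bases, a share of 0.81, against 0.71% of all rows of at least 10 FPKM. Division by a very short length may produce such values, but only 69.7% of the 99 rows have a length, under the 80% needed for the test, so it is void and the explanation stays open. No biological explanation was tested for these rows.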
